A study of Bos indicus with 8 samples.

How the data were processed

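The samples were hybridised to 2-colour oligonucleotide arrays for bovine transcripts, 8 arrays on 2 slides. Per the labels' protocols, cumulus-oocyte complexes from slaughterhouse ovaries were cultured with estradiol (1 µg/ml), 10% fetal bovine serum and adenosine (3 mM), with or without FSH, and the cumulus RNA was amplified linearly with T7 polymerase and labelled with Cy3 or Cy5 without an enzyme. All 4 arrays of one slide carried FSH in Cy5 and all 4 of the other carried FSH in Cy3, so slide and dye orientation coincide. The labels call the 4 replicates biological and give Bos indicus as the organism. A genome build is not given in the sources used here, and no coordinates are printed.

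The deposited scanner files hold the spot intensity and local background of each channel on a linear scale, with 45220 spots per array. A deposited table of the authors gives a normalized log2 ratio of Cy5 over Cy3 for each array, and the deposited series matrix holds the same log2 values turned to FSH over control, with a largest difference of 5.0e-06 after turning. Direction and scale were settled by setting each column against the scanner values (r across probes from 0.640 to 0.829). Columns of the series matrix were centred near 0, with medians of 0.0011, -0.0038, 0.0092 and 0.0082 for replicates 4, 3, 2 and 1 with FSH in Cy5, and 0.018, 0.011, 0.015 and 0.0089 for the same replicates with FSH in Cy3. How the authors corrected background and normalized is not given in the sources used here.

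Spot means and local background were processed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected by normexp (offset 50), and each array was normalized by global loess with control spots at weight 0, without scaling between arrays. Ratios were turned to FSH over control, spots of one probe were averaged, and the 2 arrays of a replicate were averaged to 1 value. Per array, negative control spots averaged 40.3 to 139.7 in Cy3 and 19.7 to 47.9 in Cy5, above the local background of 17 to 21 and 14 to 17. A dimness limit was therefore set at the mean plus 2 SD of the 153 negative control spots of that array and channel. Probes above it in at least 3 of 4 replicates in the FSH or the control channel were kept, 32229 of 43794. Signals of single channels were taken after loess and quantile normalization of average intensities.

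Gene names came from the platform annotation, which can be old. It gave 1 symbol for 21790 probes, several for 0 and none for 22004. The symbols of 18210 probes were found in the RefSeq gene table of the assembly NIAB-ARS_B.indTharparkar_mat_pri_1.0. A gene was represented by its probe with the highest mean intensity, and 3009 tested genes had several probes. Probes of enzymes with near-identical copies, such as ENO1 and LDHA, can bind more than 1 transcript, so these values are less certain.

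FSH was compared with control by limma (lmFit with an intercept, eBayes) on the 4 replicate values, with Benjamini-Hochberg adjustment at 0.05. Gene lists were tested by 2-sided camera at a preset correlation of 0.01, adjusted over the 23 lists, each with at least 5 measured members. The lists, the tests and the alternatives were fixed before the data were examined, except where stated. With camera's estimated correlation 0 lists passed, fry for movement in one direction passed 0, and fry for change in either direction passed 4 (glycolysis, cell cycle, oocyte markers and the EGF network).

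Genes were named by a rule. With fewer than 5 genes past the threshold, it takes the 10 with the lowest unadjusted p that have a symbol, the member with the largest difference from each list, and 21 genes fixed by name. Other list members were singled out after their values were seen.

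Whether replicate numbers pair the pools was checked on separate channels. Deviations from the group means correlated between FSH and control pools of the same number with r = 0.71, 0.71, 0.61 and 0.21 across probes. Hybridisation on the same arrays adds to these values, so they cannot show that the pools were paired beyond it. The numbers were taken to pair the pools, which share arrays by number. FSH pool 1 also correlated with control pool 2 (r = 0.58) and FSH pool 2 with control pool 1 (r = 0.55). FSH pool 4 correlated more with control pool 3 (r = 0.72).

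The fit was tested on simulated data for FSH against control, with 200 changed probes among 32229 at the real spreads and dye biases. It called 52.2% of the probes changed by 0.5 on the log2 scale, 76.1% of those changed by 1 and 97.0% of those changed by 2, with 8 false calls. Changed probes were drawn at random over all tested probes, dim ones included, with noise independent between probes. Spreads differed widely, with an SD of 0.042 for the dim NPPC and 1.77 for ATF3. These shares therefore do not give the power for genes with wide spreads. In simulated lists of 29 members among 12338 genes, camera with the preset correlation called 3% of unchanged lists of independent members and 33% of those sharing a correlation of 0.2, at an unadjusted p under 0.05. With an estimated correlation these shares were 0% and 1%. Simulated lists were also given a shift of -0.2 in each member. The preset correlation called 100% of them in both cases, and an estimated correlation 100% and 93%, at the same unadjusted threshold. Members of the real lists did not share 1 shift: in the glycolysis list 24 were lower and 5 higher. Its camera p with an estimated correlation was 0.0201 before and 0.462 after adjustment over the lists. The simulated list shares therefore do not give the power for real lists after adjustment.

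Alternatives covered background correction, normalization, the dimness filter, the authors' table and the series matrix, the replicate block, separate channels, each slide alone, each replicate left out, variance moderation, array weights, thresholds, the probe chosen for a gene and the correlation in camera. A median foreground, leaving out replicates 3 and 4, and 4 further gene lists were chosen after seeing the data.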

Results

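Transcript levels were measured in bovine cumulus cells, the somatic cells that surround the oocyte, after culture of cumulus-oocyte complexes for 6 h with or without recombinant human follicle-stimulating hormone (FSH, 0.5 µg/ml), the pituitary hormone that drives follicle growth. Adenosine (3 mM), a purine nucleoside, was present in both arms, so the comparison addressed the effect of FSH on cumulus transcripts in the presence of adenosine. Complexes came from follicles of 3 to 6 mm. There were 4 FSH pools and 4 control pools, with a number per pool of 10 whose unit the labels leave open. Each FSH pool was hybridised against the control pool of the same replicate number on 2 arrays of opposite dye orientation, which gave 8 arrays and 4 replicate values per gene. The median spot signal of an array lay between 55.8 and 184.3 in Cy3 and between 26.6 and 59.0 in Cy5. Between 42.5% and 78.8% of the probes on an array exceeded the negative control limit in Cy3, and between 33.9% and 86.4% did in Cy5. The control channel of replicate 3 had low shares on both arrays, 46.3% in Cy3 (68.9% to 78.8% on the other arrays with FSH in Cy5) and 33.9% in Cy5 (73.5% to 84.0% on the other arrays with FSH in Cy3). The limits of this channel were raised, at 192.1 in Cy3 (102.3 to 121.4 on those other arrays) and 82.2 in Cy5 (20.8 to 43.4). Its median signals, 184.3 and 59.0, were the highest of all arrays, so the low shares reflect the limits. The number of arrays limits the precision of all values.

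By camera with its preset correlation, 3 of 23 gene lists were lower with FSH: glycolysis (adjusted p = 1.3e-06), the cell cycle (adjusted p = 2.5e-06) and oocyte markers (adjusted p = 0.00911). With an estimated correlation 0 of 23 lists passed (adjusted p = 0.462 for glycolysis and 0.741 for the cell cycle and for oocyte markers). The estimates were 0.030, 0.19 and 0.22 for these lists. Before adjustment the camera p with them was 0.0201 for glycolysis, 0.132 for the cell cycle and 0.244 for oocyte markers. With an estimated correlation camera also rests on the 3 residual degrees of freedom of the 4 replicates. For the prostaglandin pathway the estimate of -0.030 lay below the preset 0.01, yet the unadjusted camera p rose from 0.312 to 0.359. The loss of calls therefore does not come from the estimates alone. No single gene passed the limma test. The limma fit called 0 of 32229 probes and 0 of 12338 genes, with a lowest adjusted p of 0.436 for probes and 0.318 for genes. At an unadjusted p under 0.05 there were 2888 probes (8.96%), 1404 higher and 1484 lower with FSH, and 1230 genes, 561 higher and 669 lower. Ratios had the same sign in all 4 replicates for 21.5% of the genes, against 12.5% by chance. When limma took the 8 arrays singly with the replicate as a random block, it called 632 probes and 277 genes, and with an added dye term 136 probes and 24 genes. These blocked fits count the 2 arrays of a replicate, which carry the same RNA, as separate values. They link both by a correlation common to all probes, 0.37 in the probe fit and 0.65 with the dye term. Within the slide with FSH in Cy5, 2 probes and 0 genes passed, and within the slide with FSH in Cy3, 2 probes and 1 gene passed.

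The 10 named genes with the lowest unadjusted p had the same sign in all 4 replicates, and none passed the adjusted test. Picking by p on these 4 values favours the same sign and a small SD, so neither is separate evidence. The log2 ratio of FSH over control was -0.67 ± 0.073 (SD, n = 4) for the keratin gene KRT2, -0.67 ± 0.15 for PPP1R13L, an inhibitor of p53 function, -0.52 ± 0.069 for the ubiquitin ligase gene RNF114 and -0.47 ± 0.045 for GPKOW. It was -0.43 ± 0.069 for PPP1R3C, which directs protein phosphatase 1 to glycogen, -0.37 ± 0.069 for SRP68 of the signal recognition particle and -0.35 ± 0.031 for WDR45L. Ratios above 0 were found for SVOPL at 0.60 ± 0.12, the Hippo pathway kinase gene LATS2 at 0.37 ± 0.057 and the translation factor gene EIF3H at 0.28 ± 0.036. Adjusted p in the limma fit lay between 0.318 for KRT2 and 0.413 for PPP1R13L. With the replicate block the adjusted p was 0.00154 for KRT2 and 0.00272 for RNF114. Of the 4 tested probes of RNF114, 1 had the opposite sign.

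Genes of glycolysis and glucose uptake were lower with FSH as a group in the camera test against all other genes with its preset correlation (adjusted p = 1.3e-06), and did not pass with an estimated correlation (adjusted p = 0.462). Of 29 measured members, 24 had a lower mean with FSH, 16 of them in all 4 replicates, and the list median of the log2 ratio was -0.21. Replicates 1 to 4 had list medians of -0.20, -0.15, -0.33 and -0.24. TPI1, which encodes triosephosphate isomerase, stood at -0.99 ± 0.55 (SD, n = 4), the enolase gene ENO1 at -0.99 ± 0.31, the hexokinase gene HK1 at -0.89 ± 0.49 and the lactate dehydrogenase gene LDHA at -0.68 ± 0.16. The other tested probe stood at -0.23 for ENO1 and at -0.17 for HK1. PDK4, which restrains the entry of pyruvate into the citric acid cycle, had a ratio on the other side of 0, at 0.74 ± 0.71. Over all genes 0 members passed in limma, 7 were lower and 0 higher when adjusted over the list alone, and 12 were lower and 0 higher at an unadjusted p under 0.05. On the slide with FSH in Cy5 the list median was -0.11 and the camera adjusted p 0.0898 (4.7e-08 to 0.462 over the 25 alternatives), and on the slide with FSH in Cy3 the median was -0.31. Some bright members differed between the slides: LDHA averaged 0.32 with FSH in Cy5 and -1.68 with FSH in Cy3, and the glucose transporter gene SLC2A3 averaged 0.085 and -1.39.

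**Figure D1:**
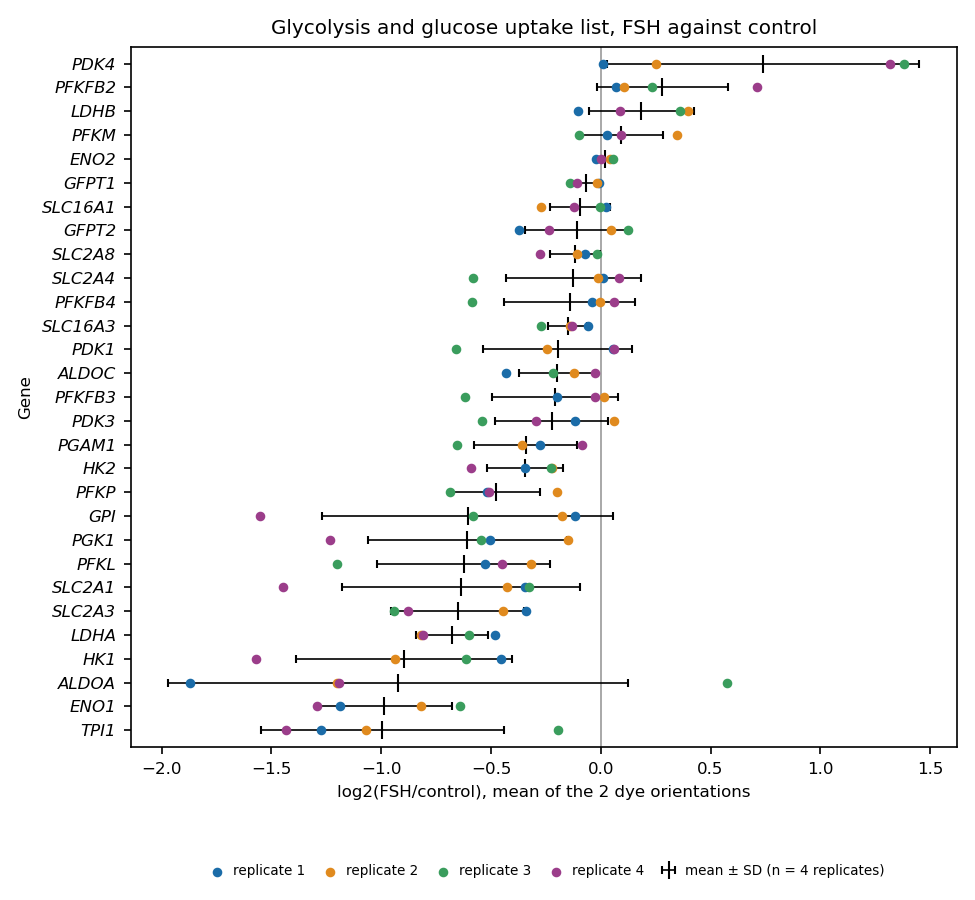
Log2 ratio of FSH over control (horizontal axis, mean of the 2 dye orientations) for the 29 measured genes of the glycolysis and glucose uptake list, with points for the 4 replicates and bars for the mean ± SD. Means of 24 genes lie below 0, with TPI1 at -0.99 and ENO1 at -0.99 the lowest.

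Cell cycle genes were also lower with FSH as a group by camera with the preset correlation (adjusted p = 2.5e-06), and did not pass with an estimated correlation (adjusted p = 0.741). Means of 37 of 44 measured members were lower, 16 of them in all 4 replicates, and the list median was -0.19. CDC20, an activator of the anaphase-promoting complex, stood at -0.32 ± 0.080 (SD, n = 4), the spindle motor genes KIF11 and CENPE at -0.32 ± 0.11 and -0.52 ± 0.22, and the replication helicase gene MCM4 at -0.24 ± 0.096. CDKN1A, which encodes the cell cycle inhibitor p21 and so acts against most other members, stood at -0.43 ± 0.13. The difference was largest for the cyclin gene CCNB2, at -0.65 ± 0.56. Over all genes 0 members passed in limma, 13 were lower at an unadjusted p under 0.05, and 5 were lower and 0 higher when adjusted over the list alone, namely CDC20, CDKN1A, KIF11, CENPE and MCM4. Replicates 1 to 4 had list medians of -0.039, -0.26, -0.15 and -0.33. The list median was -0.20 with FSH in Cy5 and -0.19 with FSH in Cy3. With each array centred on its median and no loess, it was -0.0072 and the adjusted p 0.107 (2.0e-09 to 0.741 over the 25 alternatives).

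Oocyte markers passed camera with the preset correlation (adjusted p = 0.00911), and did not pass with an estimated correlation (adjusted p = 0.741). The list was lower with FSH in replicates 3 and 4. The list median over 25 measured genes was -0.093, with medians of -0.0024, -0.0053, -0.23 and -0.12 in replicates 1 to 4. For BTG4, a regulator of maternal mRNA decay, the difference lay in the control pools. Its normalized log2 signal was 6.67, 6.60, 9.35 and 8.02 in control pools 1 to 4 and between 6.52 and 6.80 in the FSH pools. In control pool 3, 9 of the 25 markers exceeded control pools 1 and 2 by over 0.5, among them DPPA3, ZP2, ZP4, ZAR1 and FIGLA. ZP3 and OOEP, with low signal in every pool, did not. Over all genes 0 members passed in limma and 2 were lower at an unadjusted p under 0.05, and the same number was lower when adjusted over the list alone, namely RNF114 and the growth factor gene GDF9. The GDF9 probe exceeded the limit on 6 of 8 arrays in the control channel but on 2 of 8 in the FSH channel, so no size is given for it. The list median was -0.11 with FSH in Cy5 and -0.15 with FSH in Cy3, where the list did not pass (adjusted p = 0.148). In control pool 3, the share of probes above the limit was 46.3% in Cy3 and 33.9% in Cy5. The limits were raised there (192.1 and 82.2), while the median signals (184.3 and 59.0) were the highest of all arrays. Without replicate 3 the list median was -0.046 and the adjusted p 0.096 (8.2e-08 to 0.741 over the 24 alternatives). The same pools entered the other groups, and without replicates 3 and 4 the glycolysis median was -0.15 and the cell cycle median -0.15.

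**Figure D2:**
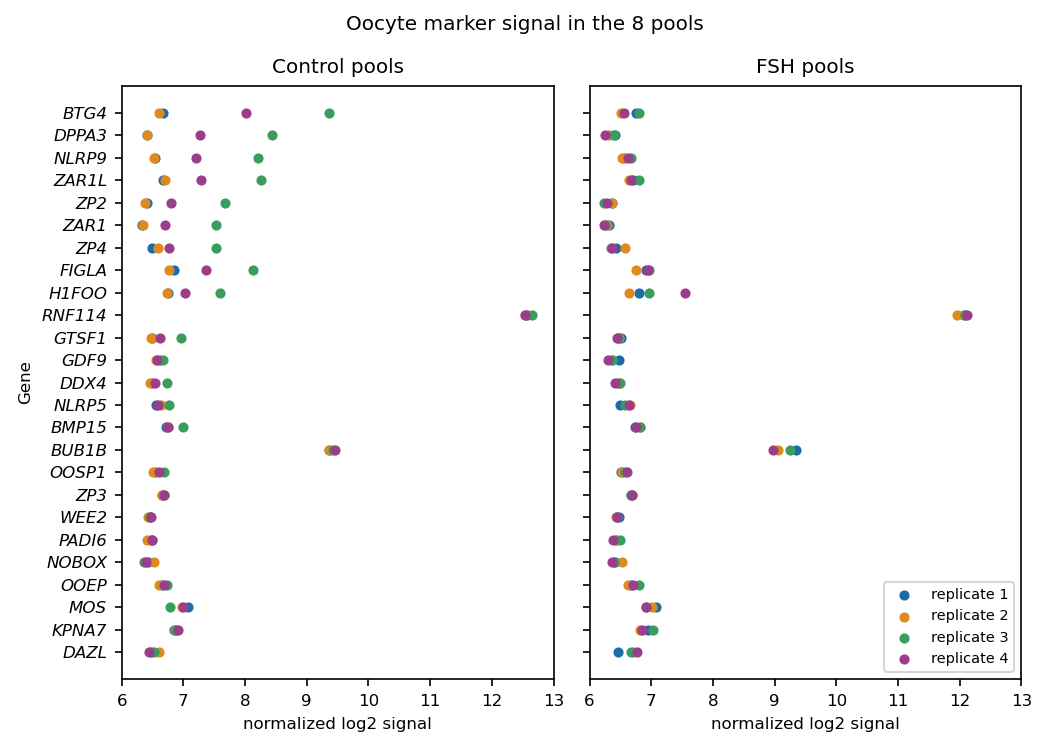
Normalized log2 signal (horizontal axis) of the 25 measured oocyte markers in the 4 control pools (left) and the 4 FSH pools (right), each point the mean of 2 arrays. BTG4 reached 9.35 in control pool 3 and 8.02 in control pool 4, against 6.67 and 6.60 in control pools 1 and 2.

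FSH is known to induce genes of cumulus expansion and EGF-like signalling, and neither list passed the test (camera adjusted p = 0.966 and 0.523). In the cumulus expansion matrix list, 9 of 16 measured members had a higher mean, 1 of them in all 4 replicates, and 7 a lower mean, 2 of them in all 4. In the EGF network list, 8 of 19 measured members had a higher mean, 3 of them in all 4 replicates, and 11 a lower mean, 4 of them in all 4. Its members IER3, an immediate early gene, at -1.26 ± 0.52 (SD, n = 4) and SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, at -0.32 ± 0.13 were lower when adjusted over the list alone. Of 21 genes fixed by name, 17 were tested, 3 were too dim (LHCGR, CREM and PDE4D), and 1, EREG, had no probe under that symbol. The FSH receptor gene FSHR stood at -0.10 ± 0.65 (SD, n = 4). In the genes of the expanding cumulus matrix, the log2 ratio was -0.087 ± 0.12 for the hyaluronan synthase gene HAS2, 0.084 ± 0.85 for TNFAIP6 and 0.0085 ± 0.41 for PTX3. PTGS2, the inducible enzyme of prostaglandin synthesis, stood at 0.16 ± 0.078, above 0 in all 4 replicates, and the EGF-like growth factor gene AREG at 0.028 ± 0.064. HAS2 exceeded the limit on 5 of the 8 arrays in the control channel and on 4 in the FSH channel, AREG on 5 and 7, and PTGS2 and TNFAIP6 each on 6 and 8, so their ratios include values near the limit. NR4A1, an immediate early nuclear receptor gene, stood at -0.24 ± 0.80. The sign turned under 10 of 24 alternatives for PTX3, 4 of 23 for TNFAIP6, 3 of 24 for FSHR, 2 of 23 for AREG, 2 of 24 for NR4A1 and 1 of 23 for HAS2. Adjusted p in the limma fit lay between 0.420 and 0.995 over the 17 genes.

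In the steroidogenesis list, 13 of 17 measured members had a lower mean, 4 of them in all 4 replicates, and 4 a higher mean, 0 of them in all 4, and the list did not pass (camera adjusted p = 0.118). STAR, which moves cholesterol into mitochondria, stood at -0.36 ± 0.26 (SD, n = 4) and CYP11A1, which cleaves its side chain, at -0.36 ± 0.48, both below 0 in all 4 replicates. HSD3B1 stood at -0.38 ± 0.74 and the aromatase gene CYP19A1 at -0.34 ± 0.49, whereas HSD17B7 stood at 0.37 ± 0.48. INHBA, which encodes a subunit of activin and inhibin, stood at -0.86 ± 0.46, but averaged -0.091 with FSH in Cy5 and -1.63 with FSH in Cy3. NT5E, the ectoenzyme that forms adenosine, stood at -0.55 ± 0.35 and the adenosine receptor gene ADORA2B at -0.26 ± 0.10, both below 0 in all 4 replicates. In the pathway that holds the oocyte in meiotic arrest, NPPC, above the limit on 6 of 8 arrays in the control channel and 7 in the FSH channel, stood at -0.029 ± 0.042, its receptor gene NPR2 at -0.0021 ± 0.16 and the gap junction gene GJA1 at -0.037 ± 0.49. The sign turned under 11 of 24 alternatives for NPR2, 4 of 24 for GJA1 and 1 of 23 for NPPC.

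**Figure D3:**
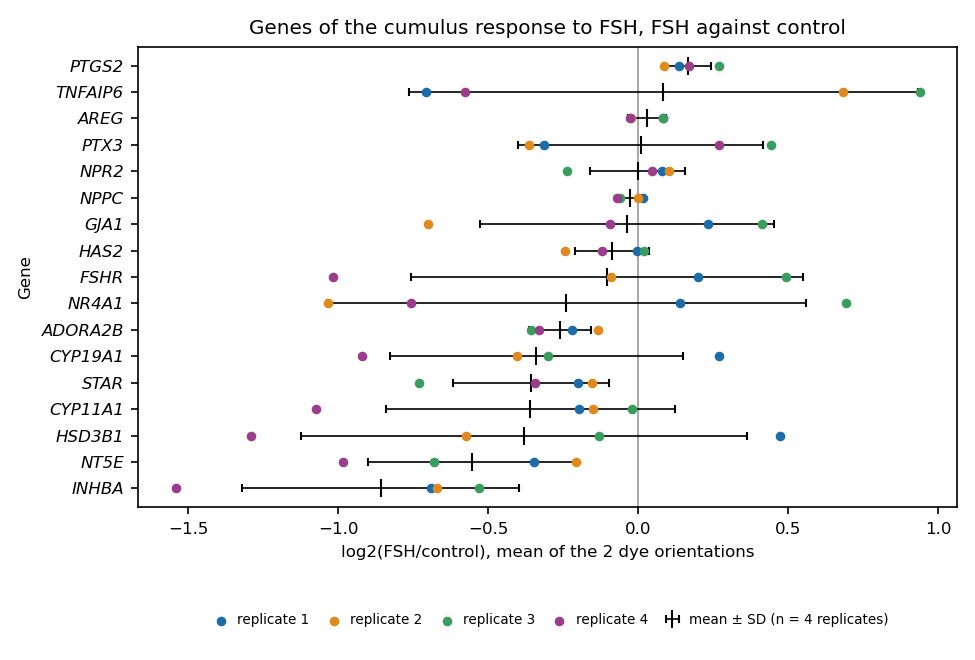
Log2 ratio of FSH over control (horizontal axis) for the 17 tested genes that were fixed in advance, with points for the 4 replicates and bars for the mean ± SD. INHBA lies lowest at -0.86 and PTGS2 highest at 0.16.

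Of the 23 gene lists, 3 passed the camera test, 0 passed with an estimated correlation and 20 did not pass. Without replicate 1, 6 lists passed, which added steroidogenesis (median -0.25, adjusted p = 0.00891), cholesterol biosynthesis and uptake (-0.081, adjusted p = 0.0139) and granulosa and cumulus identity (-0.087, adjusted p = 0.0418). Without replicate 3, CREB and immediate early targets (-0.34, adjusted p = 0.00135) and periovulatory transcription factors (-0.11, adjusted p = 0.0272) passed. Without replicates 3 and 4, TGF-beta and BMP response (-0.045, adjusted p = 0.0135) and reference genes (-0.074, adjusted p = 0.0305) passed, and with median centring the oxidative stress response (0.33, higher with FSH, adjusted p = 0.0458). Each of these 8 adjusted p was the lowest over the 25 alternatives of its list, and the highest lay between 0.741 and 0.989. With all 4 replicates, cholesterol biosynthesis and uptake had a median of -0.027 (adjusted p = 0.0803), and its adjusted p was 0.0487 with the replicate block. Its member SQLE, the squalene epoxidase gene, stood at -0.81 ± 0.45 (SD, n = 4). Steroidogenesis had a median of -0.16 (adjusted p = 0.118) and granulosa and cumulus identity a median of -0.10 (adjusted p = 0.181). For CREB and immediate early targets the median was -0.092 (adjusted p = 0.292), with the stress-response factor gene ATF3 at -1.34 ± 1.77. Periovulatory transcription factors had a median of -0.028 (adjusted p = 0.445). An adjusted p of 0.523 was shared by reference genes (median -0.13, 0.20 with median centring, PGK1 at -0.61 ± 0.45 but 0.084 with FSH in Cy5), the EGF network and ERK feedback (-0.015) and the unfolded protein and heat shock response (-0.047, DDIT4 at -0.92 ± 1.00). The same value held for the prostaglandin pathway (median 0.0042, PTGES3 at -0.36 ± 0.27), adenosine and purine metabolism (0.0010) and cAMP and PKA signalling (-0.0090, PDE8A at -0.38 ± 0.20). It held as well for the oxidative stress response (median 0.053, PRDX1 at -0.65 ± 0.76) and the insulin-like growth factor system (0.0099, IGF2 at -0.57 ± 0.92, above the limit on 6 of 8 arrays in the control channel, whose sign turned under the stricter filter). In the 19 of these 20 lists other than the EGF list, 0 members passed when adjusted over the list alone. Of the 4 tested probes of PTGES3, 2 had the opposite sign, 1 of them at an unadjusted p under 0.05.

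Apoptosis regulators had a median of 0.034 (camera adjusted p = 0.553), and GADD45G, a growth arrest and DNA damage gene, stood at -1.52 ± 0.60 (SD, n = 4), below 0 in all 4 replicates. The gap junction and natriuretic peptide list had a median of 0.00081 (adjusted p = 0.658, CTNNB1 at -0.28 ± 0.29, whose sign turned with median centring), the TGF-beta and BMP response -0.016 (adjusted p = 0.856, BAMBI at -0.73 ± 1.41) and the cumulus expansion matrix 0.0089 (adjusted p = 0.966, ADAMTS1 at -1.19 ± 1.03). Of the markers of cell types other than cumulus, the oocyte list passed with the preset correlation (adjusted p = 0.00911, and adjusted p = 0.741 with an estimated correlation), and the 3 other lists did not. Immune cell markers had a median of 0.0057 (adjusted p = 0.523, LYZ at 0.26 ± 0.30, above the limit on 6 of 8 arrays in the control channel and 7 in the FSH channel), red blood cell markers -0.0027 (adjusted p = 0.658, HBA at -0.21 ± 0.16), and markers of theca, stroma and endothelium -0.0022 (adjusted p = 0.658, MCAM at -0.60 ± 0.77). The median, the mean and the direction of the test differed in sign for 7 lists: prostaglandin pathway, adenosine and purine metabolism, oxidative stress, insulin-like growth factors, apoptosis, gap junction and cumulus expansion.

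The replicates differed in how far their ratios moved together. Across probes, which are not independent replicates, the 2 arrays of a replicate correlated with r = 0.34, 0.69, 0.73 and 0.70 in replicates 1 to 4. Between replicates, r was 0.33 for 1 and 2, 0.33 for 1 and 4, and 0.47 for 2 and 4. Replicate 3 correlated with replicates 1, 2 and 4 at 0.053, -0.049 and 0.086.

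**Figure D4:**
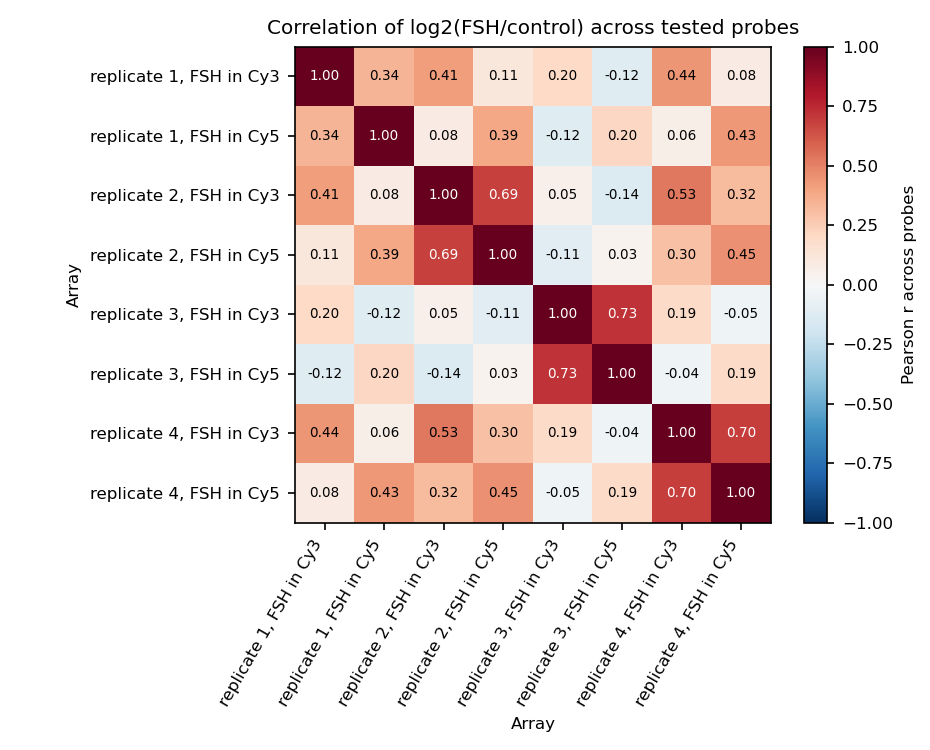
Pearson r of log2 FSH over control between the 8 arrays across the 32229 tested probes, with arrays named by replicate and dye orientation on both axes. The 2 arrays of replicate 3 correlate at 0.73 with each other and between -0.14 and 0.20 with the other arrays.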

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

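Tests of matched intensity, of dye bias of the glycolysis list on each slide, of sign patterns for the unadjusted and list counts, and of splits of the pools were written before their results were seen, and the other tests of this part were chosen only after.

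The glycolysis list was lower with FSH, with a median of -0.21. Oocyte RNA in the control pools is argued against, since the higher of the list medians in replicates 1 and 2 was -0.15, while the oocyte list had medians there of -0.0024 and -0.0053. The intensity of its probes is argued against, since 0 of 10000 random lists matched on mean intensity had a median as low (percentile 0). A dye bias of the same size on both slides is argued against, since it cancels in the mean of both orientations, and the highest of the 4 replicate medians over such means was -0.15, with all 4 of the 95% intervals below 0. The 95% intervals of this part are of a median over list genes, taken as independent. They measure the spread between genes and not that between replicates. Still open are a bias that differs between the slides, which coincide with dye orientation, chance, and an effect of FSH, as untested. The slide medians were -0.11, with a 95% interval from -0.39 to 0.023, and -0.31, with one from -0.59 to -0.11. On both slides 20 of 29 members were lower. Chance was not excluded: the adjusted p in camera was 0.462 with an estimated correlation, and 3 of 8 sign patterns reached 3 lists.

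Oocyte markers were lower with FSH in replicates 3 and 4. Dye bias is argued against, since the median of all 25 markers was below 0 in both orientations of both replicates, the highest of the 4 being -0.18, with all 4 of the 95% intervals over genes below 0. As a candidate source, oocyte RNA in the control pools of replicates 3 and 4 stays open: 9 of the 25 markers were raised in control pool 3 (36%, against 10.8% of all genes) and 5 in control pool 4, whereas ZP3, OOEP and KPNA7 were not. The log2 signal of ZP3 (6.66 to 6.69), OOEP (6.61 to 6.80) and KPNA7 (6.82 to 7.04) was low in every pool, so they may not be informative. How cumulus cells were separated from oocytes is not given in the sources used here, and 1 list gene, BUB1B, is also in the cell cycle list. RNF114 and BUB1B were bright in all pools, with a log2 signal of 12.6 and 9.36 in control pool 1.

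Replicate 3 differed from the others. An exchange of its FSH and control pools is argued against, since its mean correlation with the others across probes was 0.030, not the mirror of the 0.38 among them, although of the 119 genes over 1 higher with FSH on both of its arrays 40 were lower with FSH in both replicates 2 and 4 and 29 were higher in both. Noise of its arrays is argued against by the correlation of 0.73 between both arrays. Oocyte RNA in its control pool is argued against as the whole cause, since 119 genes were that much higher with FSH. The median of all genes, 0.0026, adds nothing here, since normalization by loess centres each array near 0. A difference between the pools stays open, and no biological explanation was tested.

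The 4 ratios allow 8 sign patterns, too few for a share under 0.05. At an adjusted p under 0.05 the real counts were 0 probes and 0 genes, with 0 as the highest of the other patterns for both. A count of 0 is reached by 8 of 8 patterns by construction and says nothing about chance. The 2888 probes at an unadjusted p under 0.05 were reached by 1 pattern, with 2081 as the highest other, and the 3 lists by 3 patterns, with 5 as the highest other. Both of these highest others came from the pattern that reverses replicate 3 alone, which gave fewer probes but more lists than the real one. Over the 35 splits of the 8 pools as separate channels, the real 0 probes at an adjusted p under 0.05 are likewise reached by 35 by construction, with 8189 as the highest other. Chance was not excluded for the real 1787 probes at an unadjusted p under 0.05, which 6 splits reached, with 13514 as the highest other. Both highest counts came from replicates 1 and 2 against replicates 3 and 4, which points to a structure of the samples. Among the 8 splits that part all 4 pairs as the real one does, the highest other counts were 1 and 949, and the splits above the real count kept pairs together. The counts of 1 and 949 came from the split that exchanges the FSH and control pools of replicate 3.

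Of 88 sets of 4 values, 7 held a value far from the other 3, where chance gives about 1 in 20, so several of the 7 may be chance. INHBA had a log2 ratio of -1.54 in replicate 4 and between -0.69 and -0.53 in the others. CYP11A1 had -1.07 in replicate 4 and between -0.20 and -0.021 in the others. NPR2 had -0.24 in replicate 3 and between 0.048 and 0.10 in the others. Reference genes had a median of 0.091 in replicate 3 and between -0.14 and -0.11 in the others. Markers of theca, stroma and endothelium had a median of -0.036 in replicate 1 and between -0.0044 and 0.0014 in the others. On the array of replicate 1 with FSH in Cy3, 42.5% of the probes exceeded the limit in Cy3, against 68.8% to 70.7% on the other arrays of its slide. The control channel of replicate 3 was not among the 7 by this rule. There 46.3% exceeded the limit in Cy3 and 33.9% in Cy5, against 68.9% to 78.8% and 73.5% to 84.0% on the other arrays of these slides. That channel had raised limits (192.1 and 82.2), while its median signals (184.3 and 59.0) were the highest of all arrays. Both arrays of replicate 1 correlated at 0.34 across probes, and those of the other replicates at 0.69 to 0.73.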

How the results depend on the processing

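A median foreground and leaving out replicates 3 and 4 were tests chosen only after the data were seen. The 0 probes and 0 genes in limma (2888 and 1230 at an unadjusted p under 0.05) stayed 0 under the alternatives except these: 632 probes and 277 genes with the replicate block, 136 and 24 with the replicate block and dye, 2 probes with FSH in Cy5 alone, 2 probes and 1 gene with FSH in Cy3 alone, and 190 and 109 at an unadjusted p under 0.05 with 1.5-fold. Without 1 replicate both counts were 0 to 0. By construction the block fits take arrays of the same RNA as separate values, linked by a correlation common to all probes. Also by construction, separate channels with the replicate block equal the ratio fit, and quantile normalization of average intensities leaves ratios as they were. The 3 lists became 0 with an estimated correlation, 3 to 6 without 1 replicate and 6 without replicates 3 and 4. Glycolysis no longer passed with an estimated correlation (-0.21) or with FSH in Cy5 alone (-0.11), cell cycle with an estimated correlation (-0.19) or median centring (-0.0072). Oocyte markers no longer passed with an estimated correlation (-0.093), FSH in Cy3 alone (-0.15), array weights (-0.048), a median foreground (-0.16) or without replicates 3 and 4 (-0.0082), and ranged from -0.16 to -0.046 without 1 replicate, with no call without replicate 3. They had too few members under the stricter filter for a value. Other lists passed under some alternatives. Without replicates 3 and 4 these were TGF-beta and BMP response (-0.045), CREB and immediate early targets (-0.18), reference genes (-0.074) and periovulatory transcription factors (-0.091), and with median centring CREB targets (-0.032) and the oxidative stress response (0.33). Cholesterol biosynthesis and uptake passed with FSH in Cy5 alone (-0.10) and with the mean of all probes of a gene (-0.030). Apart from the constructions named, the cause was not tested. Beyond the calls named here and the cholesterol list (adjusted p 0.0487), the replicate block changed no list's call. Of 1095 values of 46 named genes, 21 passed, all in the block fits, and 41 changed sign, 11 of them for NPR2 and 10 for PTX3. Signal near the negative control limit understates the difference of dim probes.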

Other observations

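All genes, lists and tests of this part were chosen only after their values were seen and are not independent evidence. Genes induced by interferon were lower with FSH in replicates 1, 2 and 4 and lay closer to 0 in replicate 3. RSAD2, an antiviral enzyme gene above the limit on 6 of 8 arrays in each channel, had log2 ratios of -2.25, -2.19, -0.29 and -1.91 in replicates 1 to 4, OAS1, which senses double-stranded RNA, had -2.02, -2.31, -0.035 and -2.16, and the RNA sensor gene IFIH1 had -1.95, -2.48, 0.22 and -1.52. Of 49 measured interferon-stimulated genes 43 had a lower mean, 25 of them in all 4 replicates, with a list median of -0.28. The camera p adjusted over 27 lists was 4.6e-12, and 0.712 with an estimated correlation. When adjusted over the list alone, 5 were lower, namely LGP2, EIF2AK2, ISG12(A), TRIM25 and PARP12. The list median was -0.18 with FSH in Cy5 and -0.35 with FSH in Cy3.

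Hypoxia-response genes had a list median of -0.35 over 30 genes, 27 of them lower, and 11 are also in the glycolysis list (camera adjusted p over 27 lists = 1.2e-09, and 0.271 with an estimated correlation). Its median was -0.13 with FSH in Cy5 and -0.39 with FSH in Cy3. BNIP3, a mitophagy receptor gene, stood at -0.84 ± 0.47 (SD, n = 4), the oxygen sensor gene EGLN3 at -0.43 ± 0.35 and the collagen hydroxylase gene P4HA1 at -0.56 ± 0.41, with its 2 dimmer probes at -0.22 and -0.13. NF-kappaB targets had a median of -0.11 over 27 genes, -0.072 with FSH in Cy5 and -0.14 with FSH in Cy3 (camera adjusted p over 27 lists = 0.0889, and 0.712 with an estimated correlation), with the brightest probe of the chemokine gene CXCL2 at -1.88 ± 0.65. In replicates 1 to 4 the list medians were -0.026, -0.051, -0.032 and -0.073, and the list means -0.25, -0.58, 0.20 and -0.44. The other 3 tested probes of CXCL2 stood at -0.59, -0.19 and -0.075, and the second of these had ratios of differing sign between replicates. Ribosomal protein genes had a median of 0.16 over 47 genes (camera adjusted p over 27 lists = 0.00535, and 0.719 with an estimated correlation), but 0.51 with FSH in Cy5 and -0.36 with FSH in Cy3. Their medians in replicates 1 to 4 were 0.070, 0.067, 0.86 and -0.20, and their means -0.055, -0.010, 0.80 and -0.24. By the means only replicate 3 was higher with FSH.

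Over all genes, 23 differed at least 2-fold on average with the same sign in all 4 replicates, 7 higher and 16 lower, and 0 of them passed in limma. PLK2, a polo-like kinase gene, stood at 1.87 ± 1.06 (SD, n = 4), the transcription factor gene CEBPD at 1.20 ± 0.78 (a dimmer probe at 0.15), and the pseudokinase gene TRIB1 at -2.58 ± 1.69. Some genes went opposite ways between replicates: the kinase gene MAP3K8 had log2 ratios of 0.17, -2.52, 3.81 and -2.12 and the stress-response gene GADD45A -0.28, -1.87, 3.28 and -1.90 in replicates 1 to 4.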
